A study of Homo sapiens with 3 samples.

How the data were processed

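The authors deposited raw UMI counts per gene and barcode for 3 libraries made with a 3′ method that partitions cells in a particle-templated emulsion (PIPseq), 1 for organoids alone, 1 for organoids with H69 cells and 1 for H69 cells alone. The deposited counts are whole numbers over 61861 features, among them an entry for the mKate2 label. The genome build hg38 and the package Seurat are named in the submitters' processing notes. The aligner, the counting program and the annotation version are not given in the sources used here. Gene coordinates come from GENCODE 29 on GRCh38, which may not be the annotation behind the counts, so genes were matched by their stable identifier.

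Cells with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs were kept, which removed 9 barcodes in all before doublet calls. The lowest barcode had 1664 UMIs in organoids alone, 5116 in the co-culture and 3112 in H69 alone, so the deposited barcodes had already been filtered at unequal depths. Doublets were called with Scrublet as built into scanpy 1.11.5. It called 0.182%, 0% and 0.0196% of barcodes, too few to have worked, and removal of the top 5% of scores was added as an alternative. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 components, 15 neighbours and Leiden clustering at resolution 1 were used on the 3 libraries together without integration (Python 3.11.15, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Clusters were named from fixed markers, and the SCLC-like clusters from the library label and markers, with no marker among their 10 leading genes. Levels and ratios of naming markers are given in places and are not independent of the naming. Those printed are GRIA2, SLC17A7 and GAP43 for neurons, VIM, HES1 and EMX2 for progenitors, COL1A2, COL3A1 and TWIST1 for mesenchymal cells, and KRT7, KRT8, KRT18, KRT19, CHGA, GRP and MYCN for SCLC. Clusters 0 and 2 were neuron-like, cluster 3 choroid plexus-like, cluster 4 mesenchymal-like, clusters 5, 6, 7 and 8 SCLC-like, and clusters 1 and 9 took no name. Of the SCLC-like cells of the co-culture 23 lay in cluster 5, 3 in cluster 6, 9 in cluster 7 and 5 in cluster 8.

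Counts were summed per library and class, for classes with at least 30 cells in both libraries. Levels are CPM of the class with exact Poisson intervals, and ratios of CPM carry exact conditional binomial intervals. With a single library per group no test between conditions exists, and both intervals cover counting error only. Log2 ratios use a pseudocount of 10 CPM. Genes with at least 50 pooled UMIs counted as measured. A gene counted as higher or lower at 2 times on that scale, and a member of a list at 1.5 times. Each of 35 gene lists was given its median log2 ratio and its percentile among 10000 random lists of the same size matched over 20 expression bins, where at least 5 members were measured. A share or ratio against 0 counts uses a floor of 3 counts over the class.

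Named genes are those with at least 100 pooled UMIs, at least 50 CPM in the higher library, an ordinary gene symbol, and a level in the other cell kind of the co-culture of at most 3 times that in the class. Of these, the 12 with the largest and the 12 with the smallest log2 ratio were named, together with the 2 highest and 2 lowest measured members of each list described. The text prints a part of them, and genes named otherwise are said to be chosen after their values were seen. Sex-linked transcripts that could show a donor's sex were left out. Results for a few genes are not reported here.

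The cell filters, clustering settings, gene lists, marker lists, thresholds, named gene rule and a first group of alternatives were set before the data were examined. Choices made after seeing the data were the scoring rule that turns marker levels into cluster names, the sub-clusters at resolution 0.5 and the progenitor-like class formed from them, the mesenchymal-like comparison, the single-barcode rule (a count of at least 10 in a barcode that is more than 10 times the class level), the thinned depths of 1500 UMIs for organoid cells and 3000 for SCLC-like cells, the choice to describe lists outside the central 95% of random lists, the genes of the H69 marker description, the 5 genes higher in each class, the part of a gene's level that carried-over RNA would make up (the measured share times the source level over the class level), and the added alternatives.

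The first group of alternatives was no filter and a stricter filter on cells, doublets kept, Leiden resolutions of 0.5 and 2, classes from a likelihood, TMM scaling with edgeR 4.0.16, median-of-ratios scaling, equal weight per cell, thinning to equal UMIs per cell, subtraction of carried-over RNA, a pseudocount of 2 CPM and count minimums of 10 and 200. TMM scaling shifted the log2 ratios of all genes by -0.23 in progenitor-like and -0.18 in SCLC-like cells. Added alternatives removed the top 5% of doublet scores, left out large single-barcode counts, subtracted RNA of mesenchymal-like cells from the neuron-like class, and took parts of the neuron-like, SCLC-like and all-organoid classes. Simulated counts had 50 genes seeded per fold, and a seeded gene counted as recovered at 1.5 times in the seeded direction. Of the genes seeded at 2, 4 and 0.25 times 100% were recovered, and 98.0% of those at 0.5 times. These values were the same in the neuron-like and in the SCLC-like comparison. Recovery by the 2-times call was not measured. The intervals covered the seeded ratio for 92.0% to 100% of genes, and 0 unseeded genes passed 2 times. Figures were drawn with matplotlib 3.10.9.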

Results

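Single-cell RNA sequencing was done on 3 libraries, 1 per condition. The first came from human brain organoids grown from the embryonic stem cell line H1. The second came from organoids of the same kind that had received NCI-H69 cells, a line of small cell lung cancer (SCLC) carrying the red fluorescent protein mKate2. The third came from H69 cells in flat culture. Per the labels the organoids were 4 to 6 weeks old, 100000 tumour cells were given per organoid, and the co-culture lasted 48 h, of which the first 24 h were in a serum-containing medium. The labels do not say whether the organoids grown alone met that medium. After filtering, the organoids alone gave 1098 cells, the co-culture 1961 and H69 alone 5094. The deposited tables hold 5433412, 22655807 and 47150989 UMIs (unique molecular identifiers) for these libraries in that order, with medians of 3998.5, 8347 and 8020 per barcode. There is no replicate library, so no difference between conditions could be tested. Ranges after a value are exact 95% intervals that cover counting error only, and levels are in CPM, the UMIs of a gene scaled to the total of its cell class.

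The organoids alone held mostly neuron-like cells and mesenchymal-like cells, with a smaller choroid plexus-like class. Neuron-like cells made up 47.3% of their barcodes (44.3 to 50.3), mesenchymal-like cells 37.2% (34.3 to 40.1) and choroid plexus-like cells 13.8% (11.8 to 15.9). In the co-culture these shares were 23.8% (21.9 to 25.7), 11.1% (9.76 to 12.6) and 12.3% (10.9 to 13.8). SCLC-like cells were 40 of 1961 barcodes there, a share of 2.04% (1.46 to 2.77), against 13 of 1098, or 1.18% (0.632 to 2.02), in organoids that had received no tumour cells. These intervals overlap. A further 50.8% of the co-culture barcodes (48.6 to 53) took no class name. In these unnamed barcodes a median of 20.4% of the UMIs came from genes with a large count in that barcode alone, against 0.497% in the neuron-like cells of the same library. Shares within a single library per condition do not show that a cell type was gained or lost, and a cluster held mostly by a single library may be that library and not a type.

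**Figure D1:**
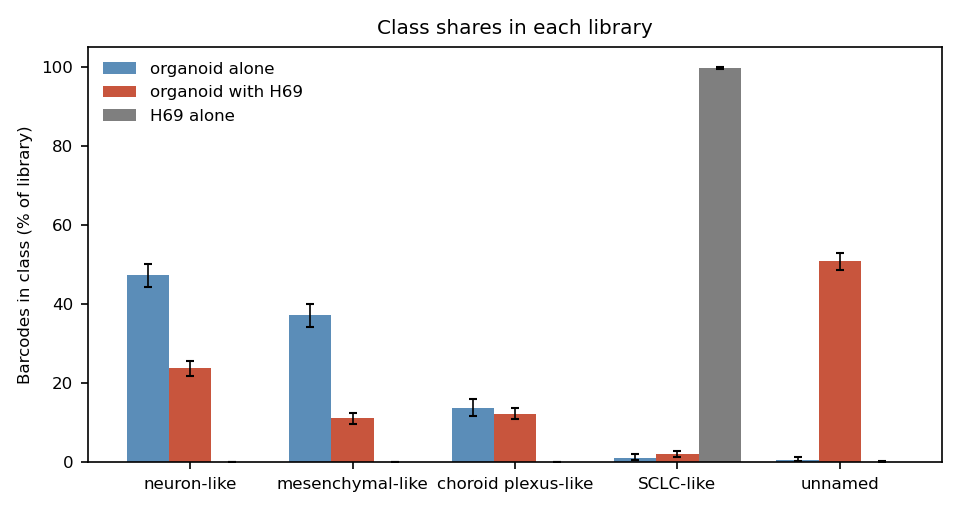
Share of barcodes in each cell class (percent, y axis) in the 3 libraries, with exact 95% binomial intervals as bars. Unnamed barcodes are 50.8% of the co-culture library and SCLC-like barcodes are 99.7% of H69 alone.

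H69 cells in flat culture had UCHL1, MYCN and keratin transcripts but very few from CHGA, GRP, INSM1 or SYP. UCHL1, a neuronal deubiquitinase used as a neuroendocrine marker, stood at 627 CPM, the oncogene MYCN at 199 CPM, the cell cycle inhibitor CDKN2A at 291 CPM and the epithelial keratin KRT8 at 145 CPM. The granule protein CHGA was at 0.128 CPM, the peptide GRP at 0.106 CPM, the regulator INSM1 at 0.786 CPM and the vesicle protein SYP at 1.28 CPM. The Notch target HES1, which opposes the neuroendocrine state, stood at 1221 CPM, VIM at 586 CPM and the collagen gene COL1A2 at 178 CPM. In the neuron-like cells of the organoids alone, SYP was at 37.4 CPM and INSM1 at 27.0 CPM. These marker genes were chosen after the data were seen. Of the SCLC naming markers, KRT8, KRT7 and MYCN passed the naming rule in the SCLC-like clusters, with KRT18 also in cluster 5. The cells were not compared with a reference profile of the line, so their identity as H69 rests on the library label.

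The mKate2 label was rarely captured. In H69 alone 91 of 5080 SCLC-like cells held an mKate2 UMI, a share of 1.79% (1.44 to 2.19), at a median of 8027 UMIs. In the co-culture 3 of 40 SCLC-like cells did, 7.50% (1.57 to 20.4), at a median of 18862.5 UMIs. None of the 1921 other co-culture cells did, at a median of 8274 UMIs, which allows a share with an mKate2 UMI of up to 0.156% on the floor of 3 counts, with an exact upper limit of 0.192%. None of the 1098 cells of the organoids alone did, which allows up to 0.273%, with an exact upper limit of 0.335%. As few H69 cells held the label, these limits do not bound the share of tumour cells. SCLC-like cells of the co-culture are therefore a class by transcript profile, with the label seen in 3 of them. Transcripts of the other cell kind were also found in each class. Carried-over RNA and barcodes that hold more than 1 cell are not told apart here, as doublet calls were too few to have worked. For SCLC-like barcodes of the co-culture, a median of 18862.5 UMIs against 8027 in H69 alone leaves the second open. Where a part of a gene's level is given below as carried over, the source is an average over its cells. In the co-culture, 23 genes that only H69 cells expressed stood in neuron-like cells at 1.24% (1.04 to 1.48) of their level in SCLC-like cells, against 0.615% in the organoids alone. They stood at 2.11% in mesenchymal-like cells, 5.10% in choroid plexus-like cells and 5.35% in unnamed barcodes. In the SCLC-like cells of the co-culture, 81 genes of organoid cells stood at 4.31% (4.06 to 4.57) of their organoid level, against 0.394% in H69 alone.

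The comparison of neuron-like cells asks how neurons differ when tumour cells share the organoid, a question the series title frames around synapses and excitability. Glutamate receptor and transmitter release lists had medians above 0 with H69, while immediate early, cholesterol synthesis and hypoxia lists had medians below 0. Most AMPA receptor, transmitter release and hypoxia genes changed by less than 1.5 times. CNIH2, an auxiliary protein that slows AMPA receptor closing, stood at 31.8 CPM with H69 and 9.13 CPM alone, 3.48 times higher (2.19 to 5.78), from 112 and 22 UMIs. NSF, which maintains surface AMPA receptors, was at 0.821 times (0.610 to 1.11). Of 13 measured AMPA receptor genes 5 were at least 1.5 times higher and 0 lower, with a median log2 ratio of 0.44. The AMPA receptor subunit GRIA2, at 2.44 times higher (2.12 to 2.81), is one of the markers that named the neuron-like clusters. FOS, the transcription factor induced within minutes of neuronal activity, stood at 52.9 CPM with H69 and 154 CPM alone, 2.91 times lower (2.43 to 3.48). The CNIH2 gene lies on chromosome 11 from 66278190 to 66285301, and FOS on chromosome 14 from 75278774 to 75282230 (GRCh38, GENCODE 29).

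Other excitatory synapse lists had medians above 0 in neuron-like cells, but not every synapse list stood out. Trans-synaptic adhesion was at 0.03, at percentile 40.1 among random lists, with 2 of 21 genes at least 1.5 times higher and 0 lower. Transmitter synthesis and transport was at -0.08, at percentile 25.5, with 0 of 9 genes higher and 0 lower. The smaller of the 2 neuron-like clusters, which had the most neuron markers, held 80 of 519 cells alone and 142 of 466 with H69, and this change in share is part of the comparison. Over the alternatives, parts of the class among them, medians ranged from 0.14 to 0.83 for NMDA, kainate and metabotropic receptors, 0.30 to 0.77 for transmitter release and 0.07 to 0.49 for the postsynaptic scaffold. With the main setting included, the receptor range rests on 20 values and the other ranges on 22. In the remaining settings fewer than 5 of the receptor genes were measured. The list of NMDA, kainate and metabotropic receptors had a median log2 ratio of 0.39, with 7 of 15 genes at least 1.5 times higher and 1 lower. Its kainate receptor subunit GRIK2 was 3.11 times higher (2.58 to 3.79), and the NMDA subunit GRIN2D, from 19 and 36 UMIs, was 2.77 times lower (1.55 to 5.11). GRM4 was 10.5 times higher (6.44 to 18.3). RNA from SCLC-like cells, at the carried-over share of neuron-like cells, would make up 1.07% of that GRM4 level. Among 24 genes of transmitter release 9 were at least 1.5 times higher and 0 lower, with a median of 0.48 that lay above every one of 10000 random lists matched on expression. SYN3, a synapsin that tethers vesicles, was 2.64 times higher (2.05 to 3.43), and PCLO, a scaffold of the release site, was 2.11 times higher (1.76 to 2.53). RAB3A, a vesicle GTPase, was at 0.879 times (0.772 to 1.00). The postsynaptic scaffold list had a median of 0.37, with 4 of 21 genes higher and 0 lower. In it the kinase CAMK2B was 2.54 times higher (1.76 to 3.74) and the scaffold DLG2 1.64 times higher (1.48 to 1.82), while DLG4 was 1.46 times lower (1.08 to 1.98). Percentiles against random lists are a description of these libraries and not a test.

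Inhibitory synapse genes gave a weaker picture, and the channel lists differed among themselves. The list of GABA and glycine receptors had a median log2 ratio of 0.11, at percentile 71.3 among random lists, and it turned to -0.22 in the larger of the 2 neuron-like clusters. GABBR2, a subunit of the metabotropic GABA receptor, was 2.08 times higher (1.49 to 2.95) and the channel subunit GABRB2 2.33 times higher (1.5 to 3.73). Potassium and HCN channels had a median of 0.24, at percentile 97.8, with 5 of 20 genes higher and 1 lower. That median turned to -0.175 in the smaller neuron-like cluster. Sodium channels were at 0.32, at percentile 93.7, with 3 of 9 higher and 0 lower. Calcium channels were at 0.15, at percentile 75.65, with 3 of 12 higher and 0 lower. The calcium channel subunit CACNA1E was 2.47 times higher (1.99 to 3.10), and the sodium channel subunit SCN3B 2.07 times higher (1.52 to 2.85). KCNK1, a potassium leak channel, was 35.4 times higher, but a single barcode held 97.2% of its UMIs, and for KCNJ6 a single barcode held 65.1%. Of 15 genes tied to homeostatic scaling 2 were higher and 1 lower, with a median of 0.21. The activity-regulated gene ARC, which removes AMPA receptors from synapses, was 2.84 times lower (1.57 to 5.33), from 18 and 35 UMIs. NTRK2, the receptor for BDNF, was 3.68 times higher, but a single barcode held 76.9% of its UMIs. Vesicular glutamate transporter SLC17A7, also a naming marker, was 1.34 times higher (1.06 to 1.70). Secretory granule genes had a median of 0.42, with 5 of 12 higher and 1 lower. SCG2 was 3.50 times higher (2.66 to 4.67) and SCG3 2.10 times higher (1.79 to 2.47). The axon genes CNTN2 and SLIT1 were 3.91 (2.20 to 7.47) and 2.15 (1.74 to 2.66) times higher.

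The lower lists of the neuron-like class held metabolic as well as immediate early genes. Of 13 immediate early genes 7 were at least 1.5 times lower and 0 higher, with a median log2 ratio of -0.70, and EGR1 was 3.15 times lower (2.36 to 4.23). The immediate early list was lower in mesenchymal-like cells too, at a median of -0.72, so its fall is not particular to neurons. Mesenchymal-like cells of the organoids alone held more FOS and EGR1 than neuron-like cells. With RNA of mesenchymal-like cells subtracted, taking all COL1A2 and COL3A1 of the class as carried over, FOS was 2.51 and EGR1 2.66 times lower. RNA from the other organoid classes was not measured in this way. Cholesterol synthesis genes had a median of -0.65, with 13 of 21 lower and 0 higher. The isomerase IDI1 was 3.16 times lower (2.80 to 3.57) and the reductase DHCR7 2.96 times lower (2.36 to 3.73). The desaturase SCD, which is not in that list, was 3.28 times lower (2.98 to 3.61). Hypoxia genes had a median of -0.43, with 8 of 20 lower and 1 higher. Among them CA9 was 5.99 times lower (4.01 to 9.17) and P4HA1 3.14 times lower (2.58 to 3.83). The glycolytic aldolases ALDOC and ALDOA were 5.01 (4.03 to 6.26) and 3.21 (2.89 to 3.56) times lower. NOTCH1 was 6.78 times lower (4.7 to 10), its target HES1 2.79 times lower (2.34 to 3.34), and the cortical progenitor factor EMX2 3.82 times lower (2.99 to 4.92). Radial glia genes had a median of -0.43, which ranged from -1.34 to -0.08 over the alternatives. The progenitor-like part of the class was 131 of 519 cells alone and 71 of 466 with H69, and within it the list stood at 0.18, so the list's fall is not separated from that change in share. EMX2 was lower within progenitor-like cells as well, at 4.01 times (2.29 to 7.43). The Notch list of neuron-like cells had a median of -0.54, which stayed between -0.70 and -0.30 over the alternatives. Collagens COL1A2 and COL3A1 were 8.56 (7.04 to 10.5) and 6.23 (5.16 to 7.58) times lower, but another organoid class of the same library held them at 26.8 and 40.5 times the neuron-like level, so RNA from other organoid cells is not excluded. HERC4 and EYS were 8.26 (6.59 to 10.5) and 6.61 (5.46 to 8.07) times lower, and 8.84 and 13.7 times lower in mesenchymal-like cells. At Leiden resolution 2 both are among the 10 leading genes of an unnamed cluster of 37 cells, all from organoids alone, so that group is not excluded as a source. Mitochondrially encoded genes had a median of 1.44, which ranged from 0.41 in the smaller neuron-like cluster to 1.73 in sub-clusters led by neuron markers. The genes ran from MT-CO1 at 1.29 times (1.16 to 1.43) to MT-ATP6 at 6.03 times (5.38 to 6.78). The heat shock genes HSPA1A and DNAJB1 were 7.48 (5.00 to 11.6) and 5.41 (4.30 to 6.88) times higher.

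In all, 452 of 10800 measured genes were at least 2 times higher in neuron-like cells with H69 and 146 at least 2 times lower. Random divisions of the neuron-like cells of organoids alone gave medians of 8 and 7.50 genes over 20 draws, with a highest count of 75 lower. Large single-barcode counts held 0.761% of the class UMIs in that library and 2.13% in the co-culture, which was not divided. These medians may therefore be too low for the co-culture, and they hold no difference between libraries. A single barcode held more than 50% of the UMIs for 136 of the higher genes, among them MEIOSIN, SLC17A2, TEP1, ZC3HAV1, NEK2-DT and KDSR-DT. With large single-barcode counts left out, 279 genes were higher. PHEX, CFAP161, FAM114A2, MAP3K4 and HPGD were higher in every class of the co-culture and are described among the other observations. The neuron-like class is a mixture that differs between the libraries. Sub-clusters named choroid plexus-like held 94 of its 519 cells in organoids alone, and no sub-cluster took that name with H69. Intermediate progenitor-like sub-clusters held 77 cells alone and 93 with H69. The cells with H69 that were led by neuron markers lay in unnamed sub-clusters of 125, 107 and 21 cells, with no neuron marker among the 25 leading genes, and in that of 107 GAP43 was the only marker. Another unnamed sub-cluster of 49 cells was led by the mesenchymal marker TAGLN. In the sub-clusters led by neuron markers, with 253 cells with H69 and 217 alone, the AMPA receptor list had a median of 0.59, cholesterol synthesis -0.77 and immediate early genes -0.36, while the G2 and M phase list turned from -0.34 to 0.21.

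**Figure D2:**
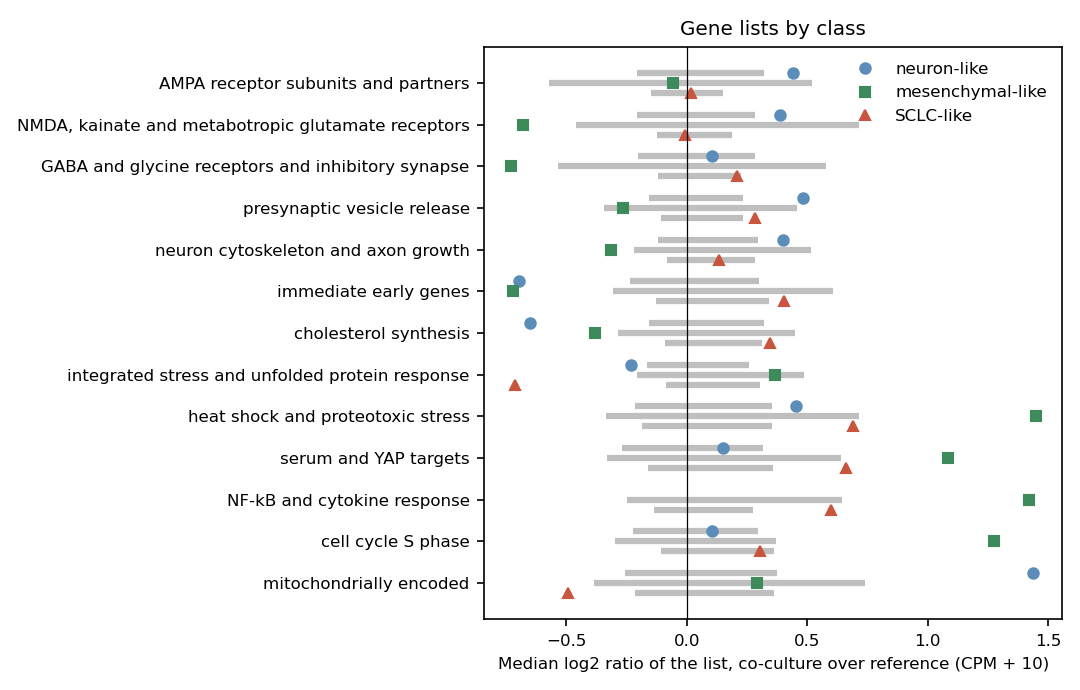
Median log2 ratio of gene lists (x axis) in 3 comparisons, with the central 95% of 10000 matched random lists as grey bars. In neuron-like cells the AMPA receptor list lies at 0.44 and immediate early genes at -0.70, and in SCLC-like cells the stress response list lies at -0.71. The NF-kB list has no point for neuron-like cells, where fewer than 5 of its members were measured.

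Progenitor-like cells gave 71 cells with H69 and 131 alone. Their sub-clusters were made separately in each library and differ in part of their leading genes. The dividing-cell genes UBE2C and PTTG1 were among the 10 leading genes of both. CDK1 and BIRC5 were among them only alone, and HOPX, FABP7, SLC1A3 and VIM only with H69. Cell state and condition are therefore not separated in the ratios. These cells are part of the neuron-like class, so the comparisons overlap and are not independent. Cholesterol synthesis had a median log2 ratio of -0.85, with 8 of 9 genes lower and 0 higher. FDFT1, the first enzyme committed to sterols, was 2.71 times lower (2.14 to 3.44), and MSMO1 2.85 times lower (1.97 to 4.20). The hypoxia genes BNIP3 and P4HA1 were 3.51 (2.34 to 5.42) and 3.24 (2.09 to 5.14) times lower. The chaperone regulator DNAJB1 was 11.6 times higher (6.09 to 24.8), and mitochondrially encoded genes had a median of 1.38. NQO1, an antioxidant enzyme, was at 0 UMIs alone and 115 with H69, at least 37.7-fold higher against a floor of 3 counts for the class. The 23 H69 genes stood in progenitor-like cells at 1.61% (1.04 to 2.38) of their SCLC-like level, a share at which carried-over RNA would make up 1.79% of this NQO1 level. At least 2 times higher were 244 of 2446 genes and at least 2 times lower 84, a higher share of 74.4% that became 50% with trimmed-mean (TMM) scaling. This class was formed from sub-clusters after the data were seen, because no cluster at the planned resolution took that name.

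Mesenchymal-like cells were compared because they formed a large class in both organoid libraries, a choice made after the data were seen. With H69 these fibroblast-like cells had more transcripts of neutrophil-attracting chemokines and of DNA replication genes. The 2 libraries came apart within the class: at Leiden resolution 2, a cluster held 390 cells alone and 11 with H69, and another 14 and 209. With no cell filter the split was 396 and 11 against 9 and 279. A change of state and a difference between the libraries are therefore not separated. CXCL8, the chemokine interleukin 8, stood at 879 CPM with H69 and at 0.947 CPM, or 2 UMIs, alone, a ratio of 928 (257 to 7665). CXCL1 was 46.0 times higher (32.1 to 68.3), CXCL3 121 times (51.6 to 373) and CXCL6 27.3 times (18.1 to 43.2). Of 14 NF-kB and cytokine genes 12 were at least 1.5 times higher and 1 lower, with a median log2 ratio of 1.42, while CXCL12 was 1.63 times lower (1.38 to 1.92). CXCL8 lies on chromosome 4 from 73740506 to 73743716.

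The extracellular matrix list of mesenchymal-like cells had a median of -0.18, with 3 of 18 genes higher and 8 lower. The mesenchymal and invasion list was at 0.38, at percentile 83.2 among random lists, with 8 of 20 higher and 5 lower. Single genes moved further. The collagenase MMP1 was 26.5 times higher (16.4 to 45.7), the gelatinase MMP9 13.8 times (7.96 to 26.2), the protease inhibitor TFPI2 88.0 times (52.3 to 161) and the metalloproteinase inhibitor TIMP1 8.77 times (8.25 to 9.34). Tenascin TNC was 4.32 times higher (3.85 to 4.86). LXN, a carboxypeptidase inhibitor, was 34.7 times higher (25.3 to 48.9). The granule protease GZMA was at 0 UMIs alone and 587 with H69, at least 112-fold higher against 3 counts, with 30.5% of its UMIs on a single barcode. Targets of serum and of the regulator YAP had a median of 1.08, with 10 of 14 higher and 0 lower, among them CCN2 at 7.24 times (6.09 to 8.66) and ACTB at 3.98 times (3.78 to 4.20). S phase genes had a median of 1.27, with 16 of 18 higher, and the replicative helicase subunits MCM7 and MCM4 were 5.66 (3.88 to 8.54) and 6.79 (4.00 to 12.4) times higher. The glycolytic enzymes PKM and ENO1 were 5.66 (4.85 to 6.64) and 4.06 (3.76 to 4.39) times higher, whereas ALDOC was 2.96 times lower (1.93 to 4.61). HSPA1A was 11.2 times higher (8.16 to 15.7).

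Genes lower in mesenchymal-like cells with H69 included FOS at 8.33 times (7.46 to 9.33) and EGR1 at 5.27 times (4.62 to 6.02), while FOSL1, a FOS relative, was 9.36 times higher (4.61 to 22.2). TXNIP, a gene induced by glucose and lost on growth stimulation, was 10.4 times lower (8.45 to 13), and HIF3A, an inhibitory hypoxia factor, 14.1 times lower (8.07 to 26.6). The transcription factors TWIST1, a naming marker, and SOX6 were 2.36 (2.03 to 2.74) and 6.96 (5.56 to 8.77) times lower, and the cadherin FAT4 6.31 times (5.03 to 7.98). Trans-synaptic adhesion genes had a median of -0.94, with 13 of 19 lower and 2 higher, among them PTPRD at 3.59 times (3.17 to 4.09). In all, 1087 of 10150 genes were at least 2 times higher and 546 at least 2 times lower. Random divisions of the mesenchymal-like cells of organoids alone gave medians of 8 and 7.50. The cells differed in depth, with medians of 14265.5 UMIs with H69 and 4432 alone.

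**Figure D3:**
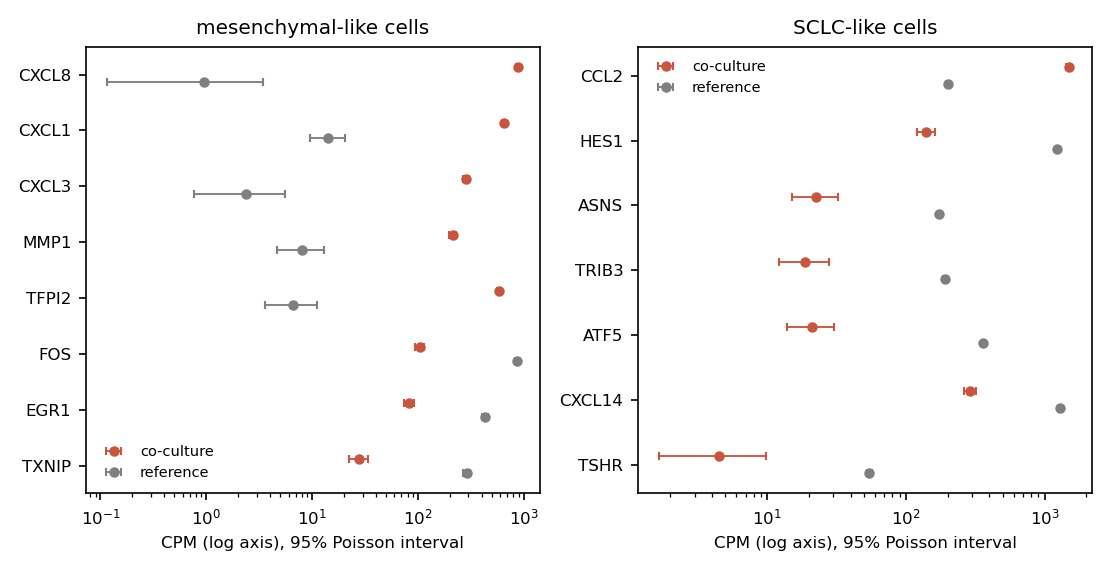
Level in CPM (log axis) of named genes in mesenchymal-like and SCLC-like cells of the co-culture and of the reference library, with exact 95% Poisson intervals as bars. CXCL8 lies at 879 CPM against 0.947 CPM in mesenchymal-like cells, and ATF5 at 21.0 CPM against 361 CPM in SCLC-like cells.

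The comparison of SCLC-like cells asks how tumour cells within organoids differ from the same line in flat culture. The list of the integrated stress and unfolded protein response had a median below 0 in the organoid, and the heat shock list a median above 0. ATF5, a transcription factor of the integrated stress response, stood at 21.0 CPM in organoids and 361 CPM in flat culture, 17.2 times lower (11.9 to 25.9). Of 27 genes of that response 14 were at least 1.5 times lower and 1 higher, with a median log2 ratio of -0.71 that stayed between -0.98 and -0.57 over the alternatives. NUPR1 was 18.8 times lower (9.92 to 41.2), the pseudokinase TRIB3 10.1 times (6.85 to 15.6) and asparagine synthetase ASNS 7.74 times (5.42 to 11.5). Outside that list, the mitochondrial enzyme PCK2 was 6.53 times lower (4.07 to 11.2) and the glycyl-tRNA synthetase GARS1 4.76 times (3.75 to 6.14). HES1 was 8.74 times lower (7.57 to 10.1). ATF5 lies on chromosome 19 from 49928702 to 49933935, and HES1 on chromosome 3 from 194136145 to 194138732.

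Other genes lower in SCLC-like cells of the organoid were the receptor TSHR at 12.1 times (5.54 to 32.9), the collagen receptor DDR2 at 6.63 times (4.37 to 10.6), COL14A1 at 5.25 times (4.02 to 7), the chemokine CXCL14 at 4.45 times (4.02 to 4.93) and UCHL1 at 3.33 times (2.94 to 3.78). GABBR2, at 101 CPM in flat culture, had 1 UMI in organoids, 134 times lower (24.1 to 5306). Its list of GABA and glycine receptor genes had a median of 0.21. MYCN, a naming marker chosen after its values were seen, was at 75.1 CPM in organoids against 199 CPM. The monocyte chemokine CCL2 stood at 1490 CPM in organoids and 200 CPM in flat culture, 7.45 times higher (7.10 to 7.82), and CCL26 was 66.5 times higher (50 to 89). RAB27B, a GTPase of vesicle secretion, was 61.8 times higher (45.5 to 84.5), and it is among the 50 genes at least 2 times higher in neuron-like, mesenchymal-like and SCLC-like cells alike. The naming markers KRT18 and KRT7 were 3.06 (2.54 to 3.67) and 2.11 (1.77 to 2.5) times higher, and KRT19 was at 0 UMIs against 6.44 CPM. CCN2 was 15.3 times higher (11 to 21), and carried-over RNA from organoid cells at the measured share would make up 38.3% of that level. Heat shock genes had a median of 0.69, with 9 of 15 higher, 1 lower and HSPA1B at 4.87 times (3.70 to 6.33). NF-kB and cytokine genes had a median of 0.60, with 6 of 12 higher, and the median fell to 0.12 in an alternative.

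In SCLC-like cells the AMPA receptor list had a median log2 ratio of 0.02 and the NMDA, kainate and metabotropic list -0.01. The transmitter release list was at 0.28 and the postsynaptic scaffold list at 0.26, both above the central 95% of random lists. With cells thinned to 3000 UMIs each, which leaves class sums of 120000 against 15240000 UMIs, these turned to -0.10 and -0.19. Trans-synaptic adhesion was at -0.16, below the central 95%, with 2 of 18 genes higher and 3 lower, and it turned to 0.15 with equal weight per cell. The neuronal gene and naming marker GAP43 was 10.7 times higher (8.02 to 14.1), and carried-over RNA at the measured share would make up 32.9% of its level. Immediate early genes had a median of 0.40, with JUNB 3.14 times (2.14 to 4.46) and IER2 2.44 times (1.76 to 3.31) higher. Cholesterol synthesis had a median of 0.34, with SQLE 3.85 times (2.99 to 4.90) and IDI1 2.60 times (2.08 to 3.23) higher. Mitochondrially encoded genes had a median of -0.49, with MT-CO2 2.37 times lower (2.21 to 2.55), which turned to 0.10 in the 17 barcodes within the UMI range of H69 alone that were also SCLC-like by likelihood.

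At least 2 times higher in SCLC-like cells were 365 of 16191 genes and at least 2 times lower 219, a higher share of 62.5% that became 45.2% with TMM scaling. Draws of 40 random cells from H69 alone against the rest gave medians of 23.5 higher and 73 lower, with highest counts of 50 and 127. Such draws hold no difference between libraries. The 10 deepest of the 40 barcodes held 57.2% of the UMIs, and TDO2, E2F7 and CCDC26 rested on a single barcode for 98.9%, 98.3% and 96.6% of their UMIs. Over all organoid cells together, 2128 of 19830 genes were at least 2 times higher with H69 and 220 lower. For 812 of the higher genes a single barcode held more than 50% of the UMIs, and without the unnamed clusters the counts were 668 and 178. Across 10184 genes, the log2 ratios of SCLC-like and neuron-like cells had a Pearson r of 0.169 and a Spearman rho of 0.080. Other pairs of classes had higher values. Pearson r was 0.285 for SCLC-like and mesenchymal-like cells and 0.349 for SCLC-like and progenitor-like cells. It was 0.461 for neuron-like and mesenchymal-like cells, which share both libraries. Genes are not independent replicates and all of these ratios share the co-culture library, so an effect of that library on several classes is not separated from a response.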

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

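Thinning and subtraction of carried-over RNA were set before the data were examined, while the count of list signs and the tests on subsets of cells were chosen after the results were seen. Neuron-like and SCLC-like cells of the co-culture gave opposite signs for 3 of the gene lists that lay outside the central 95% of random lists in both classes, a difference between groups that was not tested, since each ratio rests on 1 library per condition. Immediate early genes had a median log2 ratio of -0.70 in neuron-like cells and 0.40 in SCLC-like cells. Cholesterol synthesis was at -0.65 and 0.34. Mitochondrially encoded genes were at 1.44 and -0.49. Further lists had opposite signs but lay within that range in at least 1 class. In mesenchymal-like cells the 3 lists were at -0.72, -0.38 and 0.29 in that order, with the last inside that range. These are the signs of neuron-like cells, so they are not particular to neurons.

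Unequal UMI depth of the libraries stays open. With cells thinned to 1 number of UMIs per cell, 3 of the 3 lists kept opposite signs. Thinning keeps the expected gene proportions of each cell and cannot restore cells below the deposited cut-offs, so it cannot decide this. It shows only that the larger weight of deep cells in the sums did not set the signs. Progenitors, choroid plexus-like cells or a second cluster mixed into the neuron-like class are argued against as the whole cause, only as far as the subsets used here remove them. The larger cluster alone, the class without progenitor-like sub-clusters and the sub-clusters led by neuron markers each kept opposite signs for 3 of 3 lists. Only the last was built to leave out choroid plexus-like sub-clusters, and its cells with H69 lay in unnamed sub-clusters. A kept sign does not exclude a part: in that last subset the immediate early median was -0.36, against -0.70 in the whole class. High-UMI barcodes in the SCLC-like sum stay open: without them, and without barcodes that a likelihood did not call SCLC, 2 of the 3 lists kept opposite signs, and the mitochondrially encoded list moved to 0.10 in SCLC-like cells. Subtraction of carried-over RNA was tried before that last test and also left the 3 signs opposite. For immediate early and cholesterol genes a candidate explanation is that the reference conditions differ: SCLC-like cells are set against flat culture and neuron-like cells against organoids alone, and the serum given for the first 24 h may have reached the classes differently. The design does not separate these.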

How the results depend on the processing

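Alternatives added after seeing the data are named as added. Under the others, list medians stayed within their counting interval for 270 of 326 values in neuron-like, 24 of 36 in progenitor-like, 191 of 241 in mesenchymal-like and 187 of 236 in SCLC-like cells. For lists outside the central 95% of random lists whose counting interval excludes 0, signs turned for 0, 0, 1 and 4 values. The next ranges cover the main and all alternative settings, added ones included, in which at least 5 members were measured. These were 20 settings for AMPA receptors, 21 for immediate early genes and 22 for cholesterol synthesis. The AMPA receptor median of neuron-like cells ranged from 0.36 to 0.62, immediate early genes from -1.27 to -0.36 and cholesterol synthesis from -0.83 to -0.33. The progenitor-like class could not be formed with no filter, the stricter filter, Leiden resolution 0.5, the likelihood classes or the top 5% of doublet scores removed, so these gave no value. Counts below are genes at least 2 times higher, then lower. Where only the gene minimum or the pseudocount differed, that construction moves the count. For the rest the cause was not tested.

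A pseudocount of 2 CPM gave 766 and 359 in neuron-like, 1675 and 1074 in mesenchymal-like, and 1131 and 774 in SCLC-like cells. A minimum of 200 UMIs gave 243 and 78 in neuron-like, 59 and 28 in progenitor-like, and 711 and 244 in mesenchymal-like cells, and a minimum of 10 gave 702 and 282 in progenitor-like cells. Thinning gave 285 higher in neuron-like cells, 92 and 39 in progenitor-like, 413 and 277 in mesenchymal-like, and 841 and 1017 in SCLC-like cells. TMM gave 164 lower in progenitor-like and 238 higher in SCLC-like cells, and median-of-ratios 155 lower and 229 higher. In progenitor-like cells, keeping doublets gave 469 and 174, and resolution 2 gave 212 lower. There the class was a whole cluster (196 and 139 cells with H69, 80 and 141 alone) and not the sub-clusters, so its definition changed too. Among added alternatives, leaving out single-barcode counts gave 279 higher in neuron-like cells, the smaller neuron-like cluster 595 lower, SCLC-like barcodes within the H69 UMI range and SCLC by likelihood 429 lower, and named clusters only 668 higher over all organoid cells.

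By the same rule, medians turned as follows, added alternatives included. Sign changes of other lists are not listed. In the smaller neuron-like cluster, potassium channels were at -0.175 and ribosomal proteins at 0.33. The G2 and M phase list was at 0.084 without progenitor-like sub-clusters and 0.21 in neuron-led ones. With no cell filter, the axon growth list of mesenchymal-like cells was at 0.11. In SCLC-like cells, equal cell weights put ribosomal proteins at 0.015, thinning put the scaffold list at -0.19, transmitter release at -0.10 and glial synaptogenic factors at 0.052, and the added subset by UMI range and likelihood put mitochondrially encoded genes at 0.095. The SCLC-like values of the co-culture rest on 40 cells, of which 10 held 57.2% of the UMIs.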

Other observations

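The test on the marker split of unnamed barcodes was written before its result was seen, and the other tests in this part after. Heat shock genes at least 1.5 times higher with H69 were 6 of 14 in neuron-like, 11 of 15 in mesenchymal-like and 9 of 15 in SCLC-like cells, with 0, 0 and 1 lower. HSPH1, a chaperone that helps dissolve aggregates, was 2.68 times higher (2.21 to 3.27) in neuron-like, 5.74 times (4.5 to 7.4) in mesenchymal-like and 2.67 times (2.14 to 3.30) in SCLC-like cells. HSPA1B was 4.35 times (3.41 to 5.62), 4.64 times (3.61 to 6.05) and 4.87 times (3.70 to 6.33) higher. Of 8699 genes measured in the 3 classes, 50 were at least 2 times higher in each and 1 at least 2 times lower. HSPA1A, HSPA1B and HSPH1 are among the 50, beside PHEX, CFAP161, FAM114A2, MAP3K4 and HPGD, so an artefact of the co-culture library stays open for them too. CCL2 was among the higher ones, at 7.45 times (6.48 to 8.60) in mesenchymal-like cells. Its 15.2 times (5.74 to 57.1) in neuron-like cells came beside a level 58.9 times as high in SCLC-like cells, and at the measured share carried-over RNA would make up 73.2% of it. These genes were chosen after their values were seen.

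Glycolysis genes parted between the organoid classes. In neuron-like cells 6 of 19 were at least 1.5 times lower and 0 higher, with a median log2 ratio of -0.24. In mesenchymal-like cells 10 of 18 were higher and 3 lower, with a median of 0.88. In SCLC-like cells the median was 0.26, with ALDOA 2.55 times (2.30 to 2.81) and PGK1 2.03 times (1.90 to 2.16) higher. The difference between classes was not tested.

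The 996 unnamed barcodes of the co-culture carried 14.3% of their UMIs on long noncoding RNA genes, against 6.49% in neuron-like cells of the same library. Barcodes that all read only a shared pool of free RNA are argued against. With large single-barcode counts left out, the split between neuron and mesenchymal marker UMIs varied between them 22.0 times as much as binomial sampling. In the named organoid classes, with such counts kept, it varied 102 times as much. Smaller single-barcode counts were kept in both, so a shared pool combined with them is not excluded. Several cells under 1 barcode stay open. The median UMIs of unnamed barcodes were 0.995 times those of the named classes pooled. That median was 8331.5, against 6795.5 in neuron-like, 11077 in choroid plexus-like, 14265.5 in mesenchymal-like and 18862.5 in SCLC-like cells. The ratio depends on the classes it is set against, so it cannot decide this. Damaged cells rich in mitochondrial RNA stay open. The median mitochondrial percent of unnamed barcodes was 0.786 times that of the named organoid classes. Large single-barcode counts, a median of 20.4% of the UMIs of unnamed barcodes, were kept in its denominator and can lower the percent. That ratio, too, depends on the classes it is set against, so it cannot decide this. What these barcodes are stays open, and no biological explanation was tested.

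PHEX, CFAP161, FAM114A2, MAP3K4 and HPGD summed to between 3079 and 4751 CPM in the 5 classes of the co-culture and to between 85.1 and 100.0 CPM in the classes of the other libraries. PHEX, which encodes a bone endopeptidase, was at 1923 CPM in neuron-like and 1689 CPM in SCLC-like cells. A few barcodes with large counts are argued against, since the top barcode held a median of 1.58% of the UMIs of the 5 genes in neuron-like cells. Free RNA spread from a single class is argued against, since the highest class level was 1.54 times the lowest. The genes were picked as higher in each class, which favours even levels and weakens this argument. An artefact of this library's preparation or counting stays open and may be the simpler reading, as unrelated classes share the level.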
